A study of Mus musculus with 4 samples.

How the data were processed

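Nuclei from 4 samples of frozen, ground subcutaneous white fat of wild-type mice, 2 female and 2 male samples, were treated with Tn5 transposase, and the tagged DNA was amplified with 10 PCR cycles, per the labels' protocols. BWA, MACS2 2.1.0 and the genome build mm10 are named, per the submitters' processing notes; the version of BWA, filters, duplicate removal and any shift of reads for the Tn5 offset are not given in the sources used here. Peaks were called per library and merged into regions over the 4 libraries by the authors, per the file headers, which hold summit and interval tracks for each library and a merged track. Called peaks depend on each library's depth and background, so the number of intervals is not a measure of open chromatin alone.

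The deposited signal is the height of tag coverage at the peak, averaged by the authors over the regions linked to a gene. The deposited values of genes with 1 region were whole multiples, within 2% of a step, of 1 step per library in 100.0% of cases: 1.0 in female 1, 0.822 in female 2, 0.707 in male 1 and 0.734 in male 2. The heights were thus scaled by a factor per library before deposit, and what that factor was derived from is not given in the sources used here. Heights are coverage, not counts of reads per gene, and no count test was used. Other deposited columns give whether a peak of a library is linked to a gene, the number of regions per gene, and the highest summit over all libraries, a signal with a single value for the 4 libraries that was not used here. The number of per-library columns left unused was 0.

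The gene table paired 11993 genes with 10979 of the 12477 merged regions, up to 10318 bp upstream of a gene. In all, 4740 genes (39.5%) shared all their regions with another gene, and these genes carry the same measurement; the table held 9357 different sets of regions. Of the gene IDs, 11704 matched the reference table of mm10 genes, and 828 genes had another current symbol; the symbols of the deposited table are printed. Exon, intron and UTR positions were not used here. Positions are given in mm10, counted from 1.

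Heights were transformed as log2(height + 9), where 9 is the 5th percentile of heights above 0, rounded up. A gene needed a height above 0 in at least 2 libraries, and all 11993 met this. Sexes were compared with limma 3.58.1 in R 4.3.3, with trend and without a replicate block, and Benjamini-Hochberg adjusted p under 0.05 was taken as the threshold. Differences are male minus female; on this scale they understate the change of low genes. As the median of all genes shifted by -0.63, differences are also given relative to that median. Gene lists (26, fixed before the data were examined, as were the tests and all alternatives not said to be added) were tested with camera (correlation 0.01), camera with an estimated correlation and fry; 22 lists were tested, since the keratinocyte, male reproductive tract and Y-linked lists had no measured member and the X inactivation list served as a label check. List members were matched by deposited or current symbol, and sex chromosome genes were left out of the tested lists. Shares were compared with Fisher's exact test, two-sided. This test was fixed in advance for the place of regions only, and its use on the gene lists was added. Region sets were compared with bedtools 2.31.1, with an overlap of at least 1 bp. Python 3.11.15, pandas 2.3.3, scipy 1.17.1, numpy 2.4.6 and matplotlib 3.10.9 were used.

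Genes were named by a fixed rule: each measured member of the Y-linked and X inactivation lists; in each direction the 10 genes with the largest log2 difference among those past the threshold whose sexes do not overlap, filled where fewer passed by genes with a log2 difference of at least 1 that did not pass; up to 4 members with the smallest p of each list; and a fixed set of marker genes where measured (Pparg, Pgr and Pecam1 were). Predicted genes, microRNA genes and pseudogenes were left out, and genes with the same region count a single time.

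The test was tried on simulated libraries with the 11993 genes, the observed spread within sexes and 200 changed genes, in 20 runs. Without library-wide differences, 79.0% of genes lower by a log2 of 2 and 25.6% of genes lower by a log2 of 1 were recovered, with a median of 2 unchanged genes called lower. With the library-wide differences as observed, 89.5% and 78.3% were recovered and a median of 64.5 unchanged genes (range 45 to 83) were called lower; with centred libraries 47.9% and 21.1% were recovered and a median of 2.5 unchanged genes were called lower. Genes higher by a log2 of 2 were recovered in 48.3% of cases with the library-wide differences and in 96.2% with centred libraries, and those higher by a log2 of 1 in 0.2% and 34.7%. Alternatives covered the pseudocount (1 and 36), filters, median centring, quantile normalization, a replicate block, variance settings, a row per set of regions and each library left out. Motif searches need a genome sequence and were not run, and neither was a test on the highest value per gene.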

Results

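Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase cuts and tags open DNA, in nuclei from frozen subcutaneous white fat of wild-type mice. The series held 4 libraries, 2 from females and 2 from males, and the comparison its design names is that between the sexes. The labels do not say whether the samples of a sex came from separate animals, so the spread behind the p-values can be technical. In the limma test with trend, that spread was taken almost wholly from genes of like height, not from each gene's own samples. It also holds the library-wide differences within a sex. Values were peak heights, the scaled number of overlapping tags at a peak, averaged over the regions linked to each of 11993 genes. Read totals per library were not given in the sources used here, and the depth behind each height is therefore unknown.

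Peaks were more numerous and higher in the female libraries. Female 1 had 10238 peak intervals, female 2 had 8022, male 1 had 5484 and male 2 had 4049. The mean height per gene was 40.9 in female 1, 32.5 in female 2, 25.3 in male 1 and 16.8 in male 2. The means of the sexes, 36.7 and 21.1, differed by 15.6, against 8.47 between the females and 8.52 between the males. The exact permutation test of 2 libraries against 2 cannot give a two-sided p below 0.33. Across genes, which are not independent replicates, the Spearman correlation was 0.85 between the females and between 0.822 and 0.837 for male 1 with each female. It was 0.643 for male 2 with male 1, and 0.603 and 0.584 for male 2 with the females. The intervals of male 2 were also wider, with a median of 284 bp against 160, 165 and 171 bp in female 1, female 2 and male 1.

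**Figure D1:**
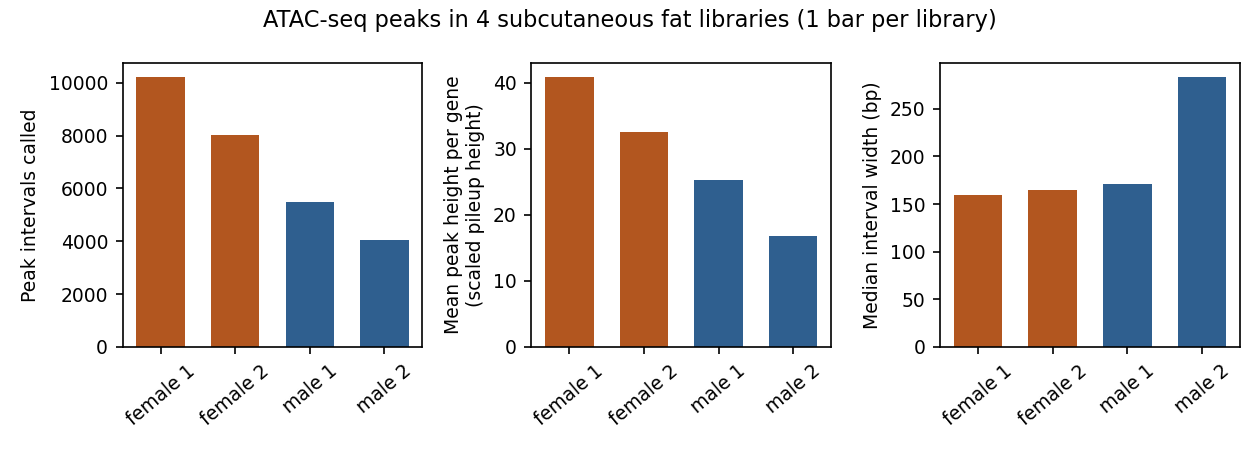
Number of peak intervals (count), mean peak height per gene (scaled pileup height) and median interval width (bp) in each of the 4 libraries, with a bar per library, females in brown and males in blue. Intervals fall from 10238 in female 1 to 4049 in male 2, and the intervals of male 2 are the widest, at a median of 284 bp.

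In the comparison of single genes, the regions of Rapgefl1, Plekhg5, Slc28a3, Mmp2 and Camsap3 were among those lower in males on the deposited scale. The limma test with Benjamini-Hochberg adjustment called 71 genes lower in males and 0 higher, with 58 separate sets of regions behind the 71 genes. At an unadjusted p under 0.05, 3768 genes were lower and 1 was higher. All 71 were autosomal, and each was lower in both males than in both females, an order that chance gives for 16.7% of genes and that 76.4% of all genes showed here. The median log2 difference over all genes, male minus female, was -0.63 on the log2(height + 9) scale, a 1.55-fold higher value of height + 9 in females. The called genes ranged from -1.89 to -1.22, so that each lay below that shift. With the libraries centred on their medians limma called 0 genes, 983 genes had an unadjusted p under 0.05, and the smallest adjusted p was 0.604. With genes at or below the 25th percentile of the mean left out, it called 0 of 8994 (2736 at an unadjusted p under 0.05, smallest adjusted p 0.135). Without male 2, limma called 0 genes at the deposited scale (986 at an unadjusted p under 0.05), without female 1 it called 19, and without male 1 it called 6391 lower and 28 higher.

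Rapgefl1 (GeneID 268480), which encodes a guanine nucleotide exchange factor-like protein, had the largest called difference on the deposited scale. Its region lay within the gene on chromosome 11 (mm10, 98839513 to 98839633, gene 98836785 to 98853005), 2831 bp from the start. The height was 29.8 ± 7.31 in females and 1.43 ± 0.981 in males (SD, n = 2 each), a log2 difference of -1.89 (SE 0.343, limma adjusted p = 4.46e-04) or -1.26 relative to the median of all genes. A region inside Plekhg5 (GeneID 269608) was linked also to Tnfrsf25, a receptor of the tumour necrosis factor family (chromosome 4, 152107637 to 152107719). Its height was 27.5 ± 6.41 in females and 1.44 ± 0.039 in males, a log2 difference of -1.80 (adjusted p = 5.75e-04) or -1.17 relative to the median.

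The other genes with the largest called differences were spread over several functions. Pdzd8, a protein of endoplasmic reticulum contact sites, had heights of 82.0 ± 18.3 in females and 27.0 ± 29.8 in males (log2 -1.63), with its region at its start on chromosome 19. Slc28a3, a nucleoside transporter, had 34.7 ± 0.952 against 6.10 ± 1.36 (log2 -1.53). Mmp2, a gelatinase that cleaves extracellular matrix, shared its region with Lpcat2, a lysophospholipid acyltransferase (chromosome 8, 92850262 to 92850546), and had 48.5 ± 3.51 against 11.8 ± 7.32 (log2 -1.51). Camsap3, which binds the minus ends of microtubules, had 25.7 ± 0.923 against 3.22 ± 1.44, from a region downstream of the gene (log2 -1.51). Elovl7, a fatty acid elongase, had 24.9 ± 7.26 against 2.87 ± 0.941 at its start on chromosome 13 (log2 -1.50). Epb4.1l1, a band 4.1 protein of the membrane skeleton, had 22.5 ± 5.02 against 2.16 ± 0.058 (log2 -1.49), Il17re, a subunit of the interleukin 17 receptor family, had 39.8 ± 13.8 against 8.42 ± 3.08 (log2 -1.47), and Jrkl had 59.6 ± 13.3 against 17.8 ± 14.8 (log2 -1.46). Their limma adjusted p-values lay between 0.0184 and 0.0486, and relative to the median of all genes the 10 genes differed by -1.26 to -0.83. In the other direction Galnt13, which encodes a glycosyltransferase, had the only log2 difference above 1, with heights of 5.38 ± 0.533 in females and 21.7 ± 7.72 in males inside the gene on chromosome 2. Its log2 difference of 1.07 did not pass (limma adjusted p = 0.0935). Relative to the median of all genes it lay at 1.70, a larger departure than that of any of the 10 genes. With libraries centred on their medians it did not pass either (limma adjusted p = 0.604).

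**Figure D2:**
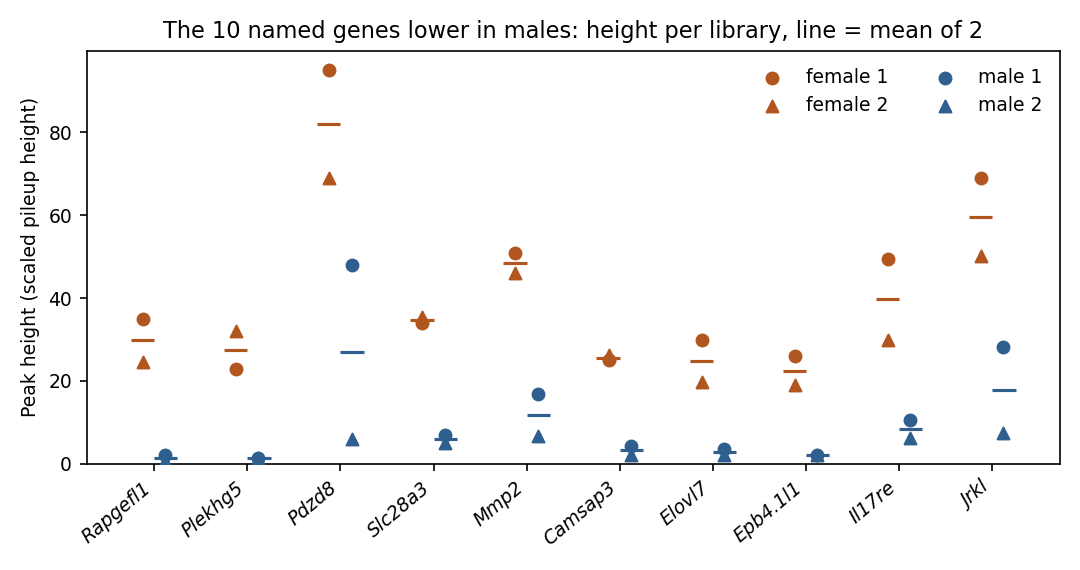
Peak height (scaled pileup height) in each library for the 10 genes named for the largest called differences, with circles for replicate 1, triangles for replicate 2 and a line at the mean of 2. Both males lie below both females at each gene, as in Rapgefl1 (means 29.8 and 1.43); with libraries centred on their medians none of these genes passes the test.

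Genes of mammary epithelium, a tissue that lies within the subcutaneous fat of female mice, were the list fixed in advance with the largest share of calls. Of its 9 measured members 2 were called lower in males, and 3 adjusted over the list alone. St14, the epithelial protease matriptase, had heights of 18.8 ± 4.51 in females and 1.80 ± 0.461 in males (log2 -1.36, limma adjusted p = 0.0283). Spint2, which inhibits that protease, had 23.1 ± 8.30 against 3.25 ± 0.597 (log2 -1.37, limma adjusted p = 0.0283), from a region 33497 bp downstream of its start. Cldn3, a tight junction protein, had 23.8 ± 1.17 against 5.70 ± 4.94 and did not pass over all genes (limma adjusted p = 0.0596), and Grhl1 had 38.7 ± 4.70 against 21.2 ± 14.5. In a test not fixed in advance for the lists, the share of calls was higher than among other genes (Fisher's exact test, two-sided, adjusted p over 22 lists = 0.0266). This test takes genes as independent, whereas the estimated correlation among the genes of this list was 0.471. The comparison was not matched on height, and whether height accounts for the share was not tested. The same test did not pass with limma without trend (3 of 9 among 416 calls, adjusted p = 0.0655) or with the replicate number as a block (5 of 9 among 6918, adjusted p = 1). Without female 1 none of the 9 was called among 19 calls (adjusted p = 1), without male 1 there were 6 among 6391 (adjusted p = 0.894), and without male 2 no gene was called.

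As whole sets, none of the 22 tested lists differed from other genes in the camera test. The smallest adjusted p was 0.346, for circadian clock and for mammary epithelium genes, and 0.993 with an estimated correlation. The median of the mammary list was -0.05 relative to all genes. The mammary list passed without female 1 (camera adjusted p = 0.00765) and without female 2 (adjusted p = 7.39e-04), but gave adjusted p = 0.978 and 0.921 where the correlation was estimated. The fry test, which asks whether the genes of a list move together and does not compare them with other genes, gave adjusted p-values of 0.169 to 0.224. No list member was called higher in males, over all genes or adjusted over the list alone.

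The medians of the 5 lists of adipocyte function lay between -0.08 and -0.02 relative to all genes. Of 15 measured adipocyte identity genes none passed over all genes and 3 were lower adjusted over the list alone. Retn, which encodes resistin, had 24.6 ± 3.40 in females against 6.40 ± 5.94 in males, from a region upstream of the gene, and Lipe, hormone-sensitive lipase, had 54.2 ± 10.4 against 21.5 ± 6.04. Cfd, adipsin, had 25.3 ± 6.08 against 7.53 ± 2.34 and the adiponectin receptor Adipor2 49.6 ± 19.0 against 21.4 ± 12.2. Pparg, the main transcription factor of adipocytes, had 24.3 ± 5.27 against 13.7 ± 1.67, or 0.08 relative to the median. Of 20 genes of lipogenesis and triglyceride synthesis none passed over all genes and 3 did over the list alone. Lpin1, a phosphatidate phosphatase, had 34.8 ± 0.336 against 8.95 ± 4.34 (limma adjusted p = 0.0516), and Agpat2, an acyltransferase of triglyceride synthesis, had 45.8 ± 15.9 against 15.7 ± 13.8. Thrsp had 34.7 ± 6.07 against 11.8 ± 5.29, and the acetyl-CoA carboxylase Acacb 37.7 ± 13.8 against 16.6 ± 9.49. The 12 thermogenic genes (2 over the list alone) included Prdm16 at 28.9 ± 3.35 against 12.2 ± 6.80, Cox7a1 at 42.6 ± 0.818 against 17.5 ± 11.2, and Ckmt1 and Ppara at relative differences of -0.46 and -0.25. The 12 lipolysis genes (0) included Npr1, the natriuretic peptide receptor, at 56.7 ± 10.4 against 21.2 ± 6.05, and Prkaca and Pde4d at -0.32 and -0.10 relative to the median. The 19 insulin and glucose genes (4) included the insulin receptor substrate Irs1 at 36.8 ± 5.51 against 11.7 ± 3.08, and Igf2r, Akt1 and Akt2 at -0.55, -0.48 and -0.35 relative to the median.

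Sex hormone lists showed no member past the threshold over all genes. Pgr, the progesterone receptor, had 14.6 ± 0.210 in females and 4.86 ± 0.124 in males (log2 -0.77, -0.14 relative to the median, limma adjusted p = 0.135), and Nr3c2, the mineralocorticoid receptor, had 72.3 ± 2.34 against 27.8 ± 23.7 (adjusted p = 0.0826). Of the 11 genes of steroid receptors and metabolism 1 was lower over the list alone, of 9 estrogen-responsive genes 1, and of 10 androgen-responsive genes 0. Hsd17b11 lay at -0.22 relative to the median of all genes. Among estrogen-responsive genes Mybl1, Ctsd and Gata3 lay at -0.43, -0.39 and -0.26, and among androgen-responsive genes Zbtb16, Acsl3, Ppap2a and Camkk2 lay between -0.29 and -0.09. The circadian clock list had 6 of 17 members lower over the list alone and none over all genes, with Npas2 at 77.5 ± 24.7 against 32.1 ± 21.5, from a region downstream of the gene, 173536 bp from its start, that was linked also to Rpl31, and Bhlhe40, Hlf and Gm129 (Ciart) at -0.44, -0.37 and -0.52 relative to the median.

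Lists for matrix and the other cell types of the pad had few calls. Among 16 extracellular matrix genes 1, Mmp2, passed over all genes and 4 over the list alone, including the collagen genes Col4a1 (29.7 ± 4.73 against 8.27 ± 1.31) and Col1a1 (23.1 ± 8.30 against 6.44 ± 2.88, from a region downstream of the gene that was linked also to Hils1) and the protease inhibitor gene Timp3 (46.0 ± 12.8 against 15.9 ± 1.45). With libraries centred on their medians Mmp2 was the only list member to pass over its list alone (limma adjusted p = 0.0154). Among 5 Schwann cell and neuron genes 1 passed, Erbb3, a neuregulin receptor, at 24.2 ± 3.04 against 4.66 ± 1.40 (log2 -1.28, limma adjusted p = 0.0436), while Pmp22, Mbp and Prx lay between -0.05 and 0.01 relative to the median of all genes. No member passed over all genes in the lists of progenitors (9 measured, Pdgfrb lowest at -0.40 relative to the median), homeobox genes (7, Irx3 at -0.39), endothelium (9, Eng at -0.36 and Pecam1 at 0.15), mural cells (4, Cspg4 at -0.32), macrophages (8, Cd9 at -0.48), T cells and innate lymphoid cells (4, Rora at -0.33), B cells and lymph node (6, Fcer2a at -0.22), neutrophils and mast cells (3, Kit at 0.03), inflammation (16, Lcn2 at -0.30) or skeletal muscle (5, Mb at -0.58). Adjusted over the list alone, members lower in males numbered 1, 0, 2, 1, 1, 2, 0, 0, 0 and 3 in these lists, in that order. No member of the keratinocyte or male reproductive tract list was measured. Among the genes of the lists above, Cldn3, Lipe, Cfd, Cox7a1, Ckmt1, Irs1, Igf2r, Nr3c2, Gata3, Acsl3, Pdgfrb, Irx3, Eng, Fcer2a, Lcn2 and Mb shared all their regions with other genes, and the nearest regions of Npr1, Gm129, Fcer2a and Lcn2 lay downstream of the gene, so these heights need not belong to the named gene.

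The sex chromosomes were examined as a check of the labels. No gene of the Y-linked list was measured, and the only Y gene in the table was Erdr1. Regions on chromosome Y outside the gene table were found in both males and neither female at 259065 to 259457, with summit heights of 73.5 and 83.0, and at 11858085 to 11858318, with 29.7 and 30.8. Of the 8 measured genes near the X inactivation centre or known to escape X inactivation none passed over all genes, and 5 were lower in males adjusted over the list alone. Kdm6a, a histone demethylase that escapes X inactivation, had 62.9 ± 15.7 in females and 23.7 ± 8.53 in males (log2 -1.15, -0.52 relative to the median, limma adjusted p = 0.0992). Kdm5c, Ftx, Mid1 and Utp14a lay at -0.38, -0.30, -0.28 and -0.23 relative to the median. The height of Mid1 averages 4 regions, of which 2 lie on chromosome Y, at 90761381 and 90767897, so it is not a measure of the X-linked gene alone. Pbdc1, which shared its region with 5530601H04Rik, lay at 0.13. Jpx had heights of 28.0 and 27.1 in females against 15.6 and 39.7 in males. Over the 256 X-linked genes the median log2 difference was 0.02 above that of autosomal genes, with a range of -0.07 to 0.06 over the 4 male-female pairs, and its sign changed with the pseudocount, the filter, the scaling and male 2 left out.

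Regions detected only in females outnumbered those detected only in males. Of 12477 merged regions, 2478 had a peak in all 4 libraries, 1608 in both females and neither male, and 58 in both males and neither female. The mixed pairings gave 404 for female 1 with male 1, 98 for female 2 with male 2, 258 for female 1 with male 2 and 112 for female 2 with male 1. The Jaccard index over bases was 0.488 between the females and 0.28 between the males, with 0.408 and 0.433 for male 1 against each female and 0.253 and 0.26 for male 2. With the same number of regions taken from each library by height, the count was 339 for both females and 254 for both males, against 210, 112, 101 and 197 for the mixed pairings in the order above. With a library left out, regions in each remaining female and no remaining male numbered 2018 (without male 2) to 4484 (without female 2). Those in each remaining male and no remaining female numbered 95 (without female 2) to 616 (without male 1). Such counts rest on fewer libraries and are not comparable with 1608 and 58. No p is given, since the 3 splits of 4 libraries into pairs cannot give one below 0.33.

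**Figure D3:**
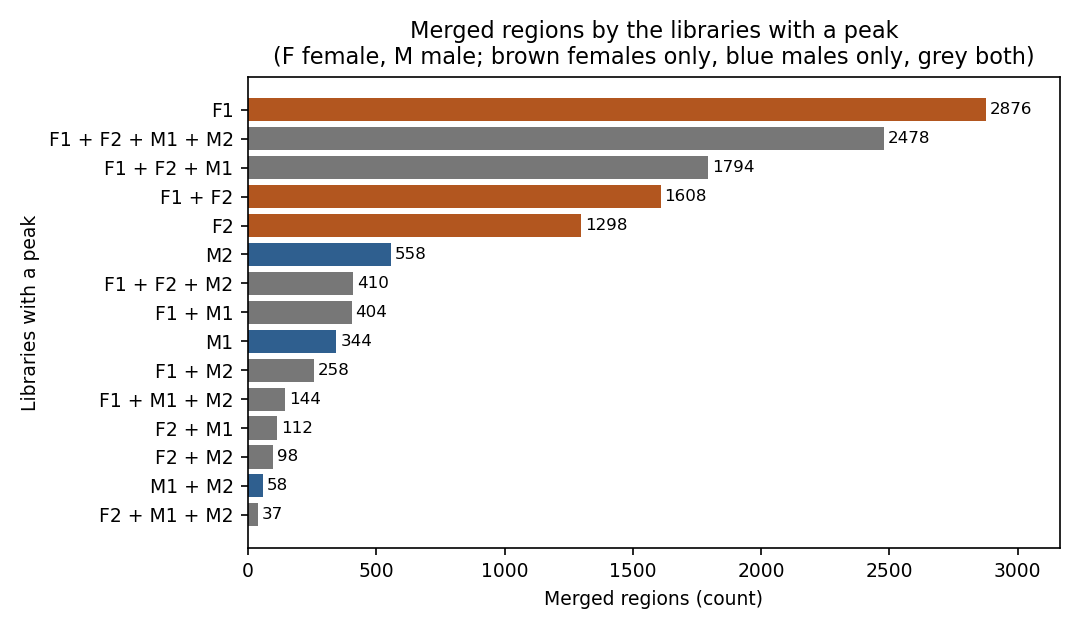
Number of merged regions (horizontal axis, count) by the set of libraries in which each had a peak (vertical axis; F female, M male). The bars show 1608 regions with peaks in both females only and 58 in both males only; with equal numbers of regions per library these were 339 and 254.

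The regions of the called genes lay away from gene starts more often than other regions, in a comparison not matched on height. With genes at or below the 25th percentile of the mean left out no gene was called. Whether height accounts for the place of the called regions was not tested. Of the 58 called sets of regions, 19 (32.8%) had a region within 1 kb of a gene start, against 7366 of 9299 other sets (79.2%; Fisher's exact test, two-sided, p = 4.08e-14). Of the 500 sets with the lowest log2 difference 67.8% did (Fisher's exact test, p = 2.48e-09), and of the 500 with the highest 81.0% did (exact p = 0.26). Without female 1 the share was 18.8% of 16 called sets, and without male 1, where 5065 sets were called, it was 79.0% against 78.8% (Fisher's exact test, p = 0.879). Without male 2 no set was called.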

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

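The tests of explanations in this part were chosen after the results were seen. The following signals were singled out because they appear in the peak tracks, whose summit heights the comparison of genes does not use on their own. On chromosome Y, regions linked to no gene were found in both males and neither female, with a lower male height of 73.515 at 259065 and of 29.689 at 11858085. At 90767897 to 90767996 on chromosome Y, near the end of the chromosome that is shared with X, both females had a peak, of 84.0 in female 1 and 77.3 in female 2, against 43.8 in male 1 and no peak in male 2; this region is linked to Mid1 and is averaged into its height in the gene comparison. In addition, 1498 merged regions were linked to no gene.

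Heights were lower in the male libraries. With the step of each library divided out, the medians of the male-female pairs moved from between -0.997 and -0.266 to between -0.716 and -0.109, where the pair nearest to 0 was male 1 against female 2, at -0.109. The males differed from each other by -0.554 on that scale, so the part that the scaling factor has in the shift cannot be told apart from differences between libraries. Differences between libraries unrelated to sex stay open too: the means of the sexes differed by 15.6, while the nearest pair of a female and a male, 7.14 apart, was closer than the libraries within a sex, 8.47 and 8.52; with the steps divided out it was 3.67 apart, against 1.44 between the females and 12.9 between the males. A difference of sex itself also stays open and was not tested apart from the libraries.

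The 71 genes called lower in males raise the question of how many exceed that shift. Simulated libraries with the observed library-wide differences gave a median of 64.5 unchanged genes called lower (45 to 83 in 20 runs). Library-wide differences that are equal for all genes on the log2(height + 9) scale could thus give as many calls. A scaling of the heights themselves shifts low genes less on that scale, and the simulated libraries had the same spread although male 2 correlated less with the rest. Whether such differences would give as many calls was not tested. The ranking of genes repeated: the 71 sets of regions lowest in a male-female pair were also low in the remaining 2 libraries. They lay at percentiles of 0.01 (the smallest 10000 lists can give) to 1.23 among height-matched random lists in 4 directions. Lists matched also on lying within 1 kb of a gene start gave at most 1.2. In the same test within sexes, 3 of 4 directions lay between 13.0 and 64.9. The fourth lay at 99.9, so libraries can share such structure apart from sex. Both males are the weaker libraries, and distance beyond 1 kb was not matched. A loss of regions in weaker libraries therefore stays open. More mammary epithelium in the female pads is a candidate source, a hypothesis that the fixed list leaves open (camera adjusted p = 0.346, median -0.05 relative to all genes). The 9 measured members ranged from Spint2 at -0.74 to Trp63 at 0.47 relative to all genes, and 1 was also in another list. Their largest heights in females were 49.5 at Esrp1, 46.4 at Rab25 and 38.7 at Grhl1. These are heights and not differences between the sexes, and Grhl1 lay at -0.11 relative to the median of all genes. The regions of Esrp1 and Rab25 were shared with other genes, and Krt8, Krt18 and Epcam were not among the genes measured. A sex difference within fat cells stays open, untested.

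Male 2 stood apart from the other libraries. It had a peak of height 82.975 in the chromosome Y region that both females lack, above its own median peak of 20.6, which argues against a female sample under a male label. In 2182 regions with an interval in each library, male 2 had the widest interval in 53.6%, which is consistent with a wider calling of its peaks; the shortest interval was 167 bp in male 2 and 76 to 86 bp in the others. Why its heights correlated less with the rest was not tested.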

How the results depend on the processing

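The number of calls depended on the processing, and the cause was not tested except where stated. From 71, all autosomal, it was 0 with a filter at the 25th percentile of the mean, with median centring and with quantile normalization, and 416 (autosomal 407) without trend. Added after seeing the data, cyclic loess gave 0, centring without trend 0, and centring without male 2 gave 17 (8 higher, 9 lower). Leaving out single libraries gave 0 (without male 2) to 6419 (without male 1; autosomal 0 to 6302), and 19 without female 1; a lone library is assumed to vary like the others. The called genes kept a median centred log2 of -0.72 (median SE 0.288), against -1.35 (0.344) as deposited. Centring removed the shift, but the p-value for a given ratio of difference to SE changed too. Mmp2 had -0.89 (SE 0.191, limma unadjusted p = 0.00096) centred and -1.51 (SE 0.383, limma unadjusted p = 7.84e-05) as deposited. How much of the loss of calls comes from the shift alone was not tested. With the replicate number as a block 6925 were called (7 higher, 6918 lower, autosomal 6783). Deviations of same-numbered libraries correlated across genes at 0.017, a value that cannot show a shift common to all genes. Mean height was higher in replicate 1 than in replicate 2 in both sexes, by 8.47 in females and 8.52 in males. The block takes up such a shift, and whether the numbers pair the libraries is not known. With the block camera called 0 lists, as without it, but the Fisher's exact test call of the mammary list was lost (5 of 9 called, adjusted p = 1), as it was without trend (3 of 9, adjusted p = 0.0655). Lists called by camera ranged from 0 to 1 with a library left out: the mammary list without female 1 or female 2, lost with an estimated correlation (adjusted p = 0.978 and 0.921).

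The X-linked difference of 0.02 was -0.056 at pseudocount 1, -0.029 with the 25th percentile filter, -0.01 with quantile normalization, -0.031 with cyclic loess and -0.023 without male 2. Regions in both females only were 939 among higher scores and 339 at equal numbers. Those in both males only were 128 at 50% overlap, 23 among higher scores and 254 at equal numbers. With a library left out, regions in each remaining female and no remaining male numbered 2018 to 4484, and the reverse 95 to 616. These rest on fewer libraries and are not comparable with the other counts. The share of called sets near a start was 18.8% to 79.0% with a library left out, the latter without male 1, where it was 78.8% among other sets and the difference was lost. The left-out libraries for regions and place were also added after seeing the data. Of the 104 named genes 13 passed as deposited, and only these could lose the threshold. All 13 lost it with median centring and with quantile normalization. The 104 comparisons without a filter repeat the same fit, since all genes met the filter. In 1402 comparisons direction and side were kept in 1141, mostly by genes that did not pass as deposited, so this number is not a measure of robust calls. In the others 63 lost and 166 gained the threshold, and 32 turned. With median centring and quantile normalization these were Jpx 0.55 and 0.46, Pbdc1 and 5530601H04Rik 0.12 and 0.072, Flt1 0.071 and 0.036, Cnn1 0.12 and 0.10, Lmod1 0.54 and 0.50, Ighd 0.09 and 0.035, Cr2 0.13 and 0.11, Csf3r 0.16 and 0.16, Gata2 0.29 and 0.26, Mybpc2 0.068 and 0.022, Prx 0.0084 and 0.013, Pecam1 0.15 and 0.088, Pparg 0.08 and 0.048, and Kit 0.032 with centring only. With a library left out, Jpx ranged from -0.57 (without male 2) to 0.41 (without male 1), Lmod1 from -0.26 to 0.08 (likewise) and Ighd from -1.14 (without male 1) to 0.063 (without male 2). The highest value per gene, a single value for the 4 libraries, and DESeq2, which needs counts, were not run. Depth per library is unknown and limits which peaks were called.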

Other observations

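The genes in this part were chosen after their values were seen. Peaks called in males only did not always mark higher male heights on the deposited scale, on which 76.4% of all genes were lower and 0.35% higher in both males. Of the 58 regions with peaks in both males and neither female, 29 had a tabulated height of their own, and 2 of these were higher in both males than in both females, 7 were lower in both males and 20 overlapped. At Cntnap5b the heights were 60.0 and 51.0 in females without a called peak, against 43.8 and 27.9 in males with one. At the start of Ddx27, an RNA helicase gene, heights were 19.0 and 11.5 in females and 28.3 and 31.6 in males (log2 0.70, 1.33 relative to the median of all genes, limma adjusted p = 0.171). Of 696 regions with a tabulated height and peaks in both females only, 610 were higher in both females and 0 in both males. Among the 20 highest of all 1608 such regions were those at Pknox1 (107.0 and 88.8 in females), Klf10 (96.0 and 53.4), Acvrl1, a receptor of the transforming growth factor beta family (82.0 and 58.4), Egr1, an immediate early transcription factor (69.0 and 54.3), and Dgat2, which makes triglycerides (67.0 and 55.1).

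Further genes known from epithelia were looked up and were not tested as a group. The region upstream of Mir200b, Mir200a and Mir429, a microRNA cluster of epithelial cells, was linked also to Ttll10 and had heights of 31.0 and 15.6 in females and 4.95 and 4.41 in males (log2 -1.20, limma adjusted p = 0.0596), and Tfap2a had 25.5 and 19.7 against 7.78 and 1.84 (adjusted p = 0.0552). Neither passed over all genes, and both comparisons are on the deposited scale, where the median log2 difference of all genes was -0.63. With libraries centred and male 2 left out, Rapgefl1, Plekhg5 and Slc28a3 were lower in male 1 than in the females, at log2 differences of -1.404, -1.413 and -1.055. Other genes were higher in male 1, such as Tmppe and Glb1, which shared a region, at 1.023. Between the independent pairs male 1 minus female 1 and male 2 minus female 2, the log2 differences correlated across genes at r = 0.194, against 0.017 between the within-sex differences.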
